A study of Mus musculus with 8 samples.

How the data were processed

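The series holds single-cell RNA sequencing of the left temporomandibular joint of mice after burn-synovectomy injury, with 1 library for each sex at days 0, 3, 7 and 21, per the labels. Per the labels' protocols, each joint was minced, digested with pronase and collagenase IV, passed through a fine filter and made into a 10x Genomics NextGEM 3' library. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, written by Cell Ranger 7.1.0, per the file headers. The submitters' processing notes name the builds GRCm39 and mm10 and Seurat 4.4.0 without saying which step each served. The rule by which the authors chose the deposited barcodes is not recorded, and counts were read as deposited. All 8 libraries share 1 table of 32285 genes. Gene symbols came from that table. Chromosome names came from GENCODE vM21, which matched 32235 gene identifiers and left 50 unmatched. Since the build was not settled, no coordinates were used. Near-identical copies (Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt) can share or lose reads in the authors' counting, so the split of reads within such a pair is uncertain.

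Cells with at least 300 detected genes and at most 15% mitochondrial UMIs were kept, which left 50783 of 62953 barcodes. Scrublet (in scanpy 1.11.5) scored doublets in each library. Its automatic threshold marked between 0 and 100 cells per library and was not used. Instead the highest-scoring cells were removed at a rate of 0.8% per 1000 cells, which took 3.49% to 7.36% of a library and left 47981 cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without mitochondrial, ribosomal, hemoglobin and listed sex-chromosome genes, were scaled and clipped at 10 standard deviations. Then 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1.0) gave clusters, with no integration between libraries. Each cluster was named from marker genes. A name needed at least 3 markers with a log2 fold of at least 1 over the median cluster, and a lead of 1 in mean score or of 3 among the 10 leading genes over the next class. The markers were chosen before the data were examined, but these naming thresholds were set after seeing the clusters. Clusters that met no name, 8.94% to 23.2% of a library's cells, stayed unnamed. They were left out of the gene tests but counted among the kept cells of each share.

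Counts were summed per library and cell class, because libraries and not cells are the unit of replication. The 6 classes with most cells and at least 30 cells in every library were tested. The edgeR 4.0.16 quasi-likelihood F test (TMM normalization, filterByExpr, R 4.3.3) was fitted with terms for day and sex, which leaves 3 residual degrees of freedom. Sex was tested as female minus male over the 4 days, and days 3, 7 and 21 against day 0 over both sexes. A further fit tested whether the response to injury (days 3, 7 and 21 together against day 0) differed by sex, with 2 residual degrees of freedom, on the genes that passed the filter of the first design. That filter was chosen after a first fit with the interaction design's own filter had been seen, and both results are given. Adjusted p values are Benjamini-Hochberg values over the genes of a class, with a threshold of 0.05. The spread behind each p value by sex or day is that between these 8 libraries around an additive model of sex and day. For the interaction it is the spread of the injured libraries alone, since that fit matches both day 0 libraries exactly. The labels do not say whether a library is a single mouse or a pool. CPM values (counts scaled to a common library total) use TMM factors, except in the check of sex labels, and errors of log2 changes are standard errors from the F statistic.

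Shares of classes were tested with the same edgeR model on numbers of cells, with all kept cells as library size, and each share has an exact binomial 95% interval that covers counting error only. For 26 gene lists, camera (limma 3.58.1) was run on log2 CPM (prior count 3) with a preset correlation of 0.01, beside camera with an estimated correlation and fry, on lists with at least 3 measured members, with Benjamini-Hochberg adjustment over 151 pairs of list and class in a contrast. Camera with an estimated correlation has only the 3 residual degrees of freedom of the fit, so a call after adjustment over 151 pairs was unlikely from the start. Each day's difference between the sexes rests on 1 library per sex and has no test. For it, the median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, with 1 CPM added.

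The comparisons, tests, gene lists, filters (apart from that of the interaction), most of the alternative settings and the rule for naming genes were chosen before the data were examined. The rule took, per class and contrast, the 2 higher and the 2 lower genes with the largest change among those past the threshold with an absolute log2 change of at least 1, a mean of at least 50 CPM and the same sign in every pair of libraries. It added up to 4 members of each described list with the smallest adjusted p, and the 2 genes with the smallest adjusted p for the interaction. The gene called for the interaction in erythroid cells is not reported here. Genes named outside the rule are said to be chosen after their values were seen.

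The test was run on simulated counts drawn from the real means, library sizes and spread, with 100 genes changed 2-fold and 100 changed 4-fold. For sex, it recovered 50% (erythroid cells, 11884 genes) to 80% (neutrophils, 14148 genes) of the genes changed 2-fold and 85% (B or plasma cells, 12848 genes) to 98% (neutrophils) of those changed 4-fold. For day 3, it recovered 13% (fibroblasts, 13780 genes) to 60% (neutrophils) of the genes changed 2-fold and 64% (erythroid cells) to 89% (endothelial cells, 12116 genes) of those changed 4-fold. False calls made up 5.9% to 12.8% of the calls, above the nominal 5%.

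Alternatives were DESeq2 1.42.0 size factors within edgeR, the DESeq2 Wald test, no low-count filter, stricter cells (at least 500 genes and at most 10% mitochondrial UMIs), doublets kept, classes from Leiden resolution 2.0, the day or the sex term left out, X and Y genes left out, and each library left out in turn. Chosen after seeing the data were fits without the day 7 libraries, fits of single clusters, the interaction design's own filter, and leaving out each injured library in the interaction fit. Leaving out a library leaves its group without a library, and the other library of that day is then assumed to vary like the other groups. In the tests by sex and of the interaction, that other library is fitted exactly by its day term, so the whole day drops out. Leaving out either library of a day is then nearly the same check, which makes 1 check per day and not per library. A residual degree of freedom is also lost, so a lost call need not come from the library left out. Scaling with DESeq2 size factors moved the median log2 change of all genes by between −0.023 and 0.011. Python was version 3.11.15.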

Results

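Gene expression was measured in single cells of the left temporomandibular joint, the hinge of the jaw, in mice with burn-synovectomy injury. Joints of females and of males were collected at days 0, 3, 7 and 21 after injury, and each sex and day gave 1 library, so the 8 groups had no replicates and tests rested on 4 libraries per sex or 2 per day. The labels name the injury for all 8 libraries, day 0 included, and do not say whether day 0 joints were taken before or just after it, or whether a library is 1 mouse or a pool. Libraries of days 3, 7 and 21 are called injured here. Total UMIs were 46120152 in the female and 58091548 in the male library of day 0, 46423779 and 88175320 at day 3, 41263892 and 48300082 at day 7, and 44807354 and 60583941 at day 21. Of 62953 barcodes, 47981 were kept as cells, from 4012 in the female day 3 library to 8494 in the male day 3 library. The median UMIs per kept cell ranged from 3182 in the female day 7 library to 6332 in the female day 3 library.

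The sex labels were checked with the sex-chromosome genes, and all 8 libraries matched their labels. Xist (ENSMUSG00000086503), the X-linked RNA that silences an X chromosome in females, stood at 419 to 644 CPM (counts scaled to a common library total) in the 4 female libraries and at 0.0840 to 3.10 CPM in the 4 male libraries. The Y-linked genes Ddx3y and Uty stood at 46.1 to 75.2 CPM in the male libraries and at 0.116 to 0.868 CPM in the female libraries. Eif2s3y was at 44.3 to 54.6 CPM and Kdm5d at 7.94 to 14.1 CPM in males, against 0.0233 to 0.5 CPM in females.

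The kept cells were mostly of the blood and bone marrow lineages. Neutrophils were the most numerous named class with 15341 cells, followed by B or plasma cells (5420), erythroid cells (4259), endothelial cells (3751), macrophages or monocytes (3424) and fibroblasts (2891). Hematopoietic progenitors (1812 cells), T or NK cells (1106) and mural cells (688) also reached 30 cells in every library, while chondrocytes were 0.0760% (male day 0) to 1.21% (female day 7) of a library. Neutrophils were 47.1% (95% interval 46.0% to 48.3%) of the female and 45.1% of the male day 7 library, against 28.3% and 29.9% at day 0. In the female day 3 library they were 14.1%, against 30.6% in the male one, while macrophages or monocytes were 13.9% in that female library against 6.52% in the male and 5.10% in the female day 0 library. Among neutrophils, cluster 1 made up 49.3% and 41.5% of the class in the female and male library at day 7 and at most 15.7% at any other day. Cluster 2, with nearly the same leading genes (Il1b, Cxcl2 and Clec4d among them), was 31.0% and 36.1% at day 0 and 4.89% and 10.9% at day 7. Among macrophages or monocytes, the C1qb-high cluster 15 was 78.7% of the class in the female and 32.9% in the male day 3 library, against 16.1% and 19.1% at day 0.

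No class share passed the test in any contrast. By edgeR, 0 of 14 classes were called by sex, at day 3, day 7 and day 21 and for the interaction, with 1, 2, 3, 0 and 0 classes at an unadjusted p under 0.05. The smallest adjusted p values were 0.0686 at day 7, for B or plasma cells (log2 change −1.23 ± 0.37) and fibroblasts (−1.51 ± 0.44), both lower in both sexes. These counts depended on which library was left out. At day 7, 3 classes were called without the female day 3 library, 5 without the male day 3 library and 1 without the female day 7 library. At day 3, 2 were called without the male day 3 library and 1 without either day 7 library. By sex, 1 was called without either day 7 or the female day 21 library, and at day 21, 1 without either day 7 or the male day 21 library.

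**Figure D1:**
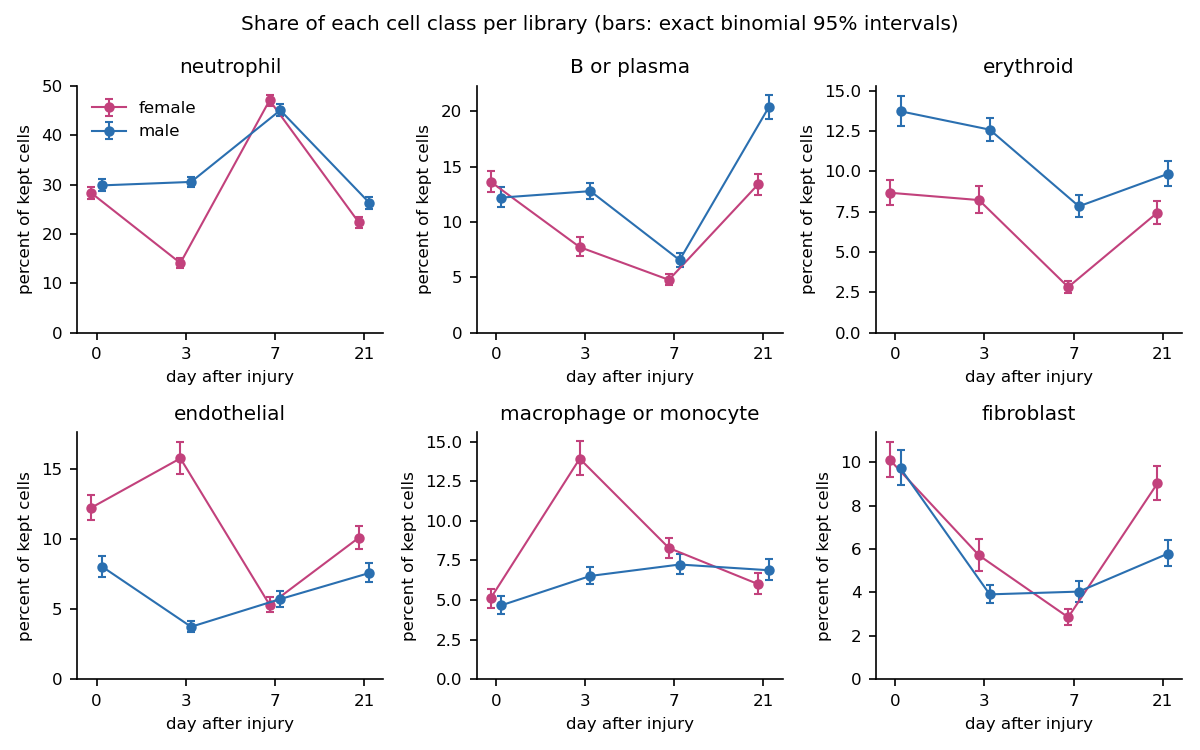
Share of kept cells (percent) in each of the 6 main cell classes by day after injury, 1 point per library, females and males in separate colours, with exact binomial 95% intervals as bars. Neutrophils were 47.1% and 45.1% of the female and male day 7 libraries, and no class share passed the test between libraries.

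The comparison by sex, which the series title names, asked which genes differed between female and male libraries over the 4 days. Neutrophils of females held less Hspa1a, an inducible heat-shock chaperone, with 12.5 against 46.0 CPM in males (log2 change −1.90 ± 0.13, adjusted p = 1.12e-05, 4 libraries per sex). Its near-identical copy Hspa1b was also lower in females, at 17.9 against 57.5 CPM (−1.78 ± 0.25, adjusted p = 0.0071). Hspa1a belongs to the list of dissociation-stress genes, and a difference in digestion between libraries was not tested. Neutrophils of females held more Irf7, a regulator of the interferon response, at 28.2 against 17.5 CPM (0.69 ± 0.11, adjusted p = 0.0255). They also held more of the chemokines Ccl4 (187 against 105 CPM, 0.81 ± 0.14, adjusted p = 0.0311) and Cxcl2 (829 against 560 CPM, 0.57 ± 0.10, adjusted p = 0.0311). Each of these genes differed in the same direction on all 4 days. Of 21 interferon-response genes measured, 2 (Irf7 and Bst2) were called higher over all genes and 15 when adjusted over the list alone (camera adjusted p = 3.65e-06, and adjusted p = 0.749 with an estimated correlation). The median log2 ratio of this list between the 2 libraries of a day was −0.08 at day 0, with 8 of 21 higher in the female library, and 0.50, 1.23 and 0.78 at days 3, 7 and 21. Of 13 inflammatory cytokines and chemokines, 2 were called higher, and 6 adjusted over the list alone (camera adjusted p = 0.0406, and adjusted p = 0.783 with an estimated correlation), and their median was −0.10 at day 0. Gm10800 (ENSMUSG00000075014), a predicted gene, was higher in the same female neutrophils, at 488 against 203 CPM (1.18 ± 0.16, adjusted p = 0.00569). Within a single neutrophil cluster, cluster 0, the change of Ccl4 turned to −0.45. Hspa1a, Hspa1b and Gm10800 passed with any 1 library, and so any 1 day, left out. Irf7 and Bst2 lost the call without any day 7 or day 21 library, Ccl4 without the male day 7 or either day 21 library, and Cxcl2 without either day 3 or day 21 library.

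In B or plasma cells, 3 of 14 genes of neutrophils and 2 of 10 of macrophages were called higher in female libraries. For the macrophage list, camera gave adjusted p = 6.46e-05, and adjusted p = 0.749 with an estimated correlation. At day 7, 5 of its 10 genes were higher in the female library. Ltf (lactoferrin, a neutrophil granule protein) stood at 111 against 38.1 CPM (1.89 ± 0.24, adjusted p = 0.00312). Lyz2 (lysozyme of myeloid cells) stood at 273 against 93.7 CPM (1.74 ± 0.25, adjusted p = 0.00739) and Chil3, a chitinase-like protein of myeloid cells, at 87.7 against 19.6 CPM (2.27 ± 0.25, adjusted p = 0.00112). Of 14 neutrophil genes, 3 were called higher over all genes (Ltf, Lcn2 and Mmp8) and 11 adjusted over the list alone (camera adjusted p = 3.56e-06, and adjusted p = 0.749 with an estimated correlation). Few cells held much of such RNA, as 4 of 731 and 4 of 696 cells of the female day 0 and day 21 libraries had 76.5% and 92.3% of the S100a8 and S100a9 UMIs of the class. The other cells held means of 2.44 and 2.60 in the female and male library at day 0, 2.09 and 4.23 at day 3, 5.58 and 3.02 at day 7 and 2.14 and 1.57 at day 21. Lyz2 lost the call without either day 21 library and Lcn2 without any day 0 or day 7 library. With doublets kept, the changes turned to −0.29 for Ltf and −0.07 for Lyz2, and in B cell cluster 6 alone to −0.86 for Ltf and −0.44 for Lcn2. H2-DMb2, which helps load peptides on MHC class II, was higher in female B or plasma cells at 99.2 against 58.5 CPM (0.74 ± 0.14, adjusted p = 0.0341), but lost the call without any 1 of the 8 libraries. It was the only one of 9 MHC class II genes called over all genes, while 9 were higher adjusted over the list alone (camera adjusted p = 1.39e-06, and adjusted p = 0.749 with an estimated correlation). The mix of clusters differed with it, since cluster 6, led by MHC class II genes, was 32.0%, 70.3%, 51.4% and 65.4% of the class in females at days 0, 3, 7 and 21, against 25.8%, 40.98%, 17.4% and 51.7% in males. Within cluster 6 alone the change of H2-DMb2 was 0.17 (adjusted p = 0.871). Female erythroid cells likewise held more Cxcl2 (28.2 against 7.30 CPM, 1.75 ± 0.22, adjusted p = 0.0237) and Tyrobp, a signalling adaptor of myeloid cells (39.2 against 15.3 CPM, 1.32 ± 0.17, adjusted p = 0.0237). Both lost the call without any day 3 or day 7 library. On those days the low-UMI cluster 21 was 54.2% and 38.4% of the erythroid class in females and 14.9% and 9.98% in males.

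Endothelial cells of females held far less hemoglobin RNA than those of males. Hbb-bt, a beta globin, stood at 154 against 1644 CPM (−3.72 ± 0.39, adjusted p = 0.00165) and Hbb-bs at 962 against 6567 CPM (−3.02 ± 0.42, adjusted p = 0.016), each lower in the female library on all 4 days. Of 7 hemoglobin and erythroid genes, 5 were called lower over all genes and 7 adjusted over the list alone (camera adjusted p = 3.48e-10, and adjusted p = 0.749 with an estimated correlation). Both globins lost the call without either day 7 library. Among 32 oxidative phosphorylation genes in the same cells, 0 were called over all genes and 21 were higher in females adjusted over the list alone. Their median log2 change was 0.33 (camera adjusted p = 2.94e-08, and adjusted p = 0.749 with an estimated correlation). Gm10801, another predicted gene, was higher in female endothelial cells, at 260 against 105 CPM (1.19 ± 0.17, adjusted p = 0.0222), a call lost without any day 7 or day 21 library.

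Fibroblasts of females held less Eln, the gene of elastin, at 70.8 against 226 CPM (−1.59 ± 0.19, adjusted p = 0.0241), and less Mdk, the growth factor midkine, at 45.4 against 136 CPM (−1.54 ± 0.16, adjusted p = 0.0177), on all 4 days. Both calls were lost without either day 0 library or the male day 7 library. Of 25 proliferation genes in fibroblasts, 0 were called over all genes, and 18 were higher in females adjusted over the list alone, with a median log2 change of 1.33 (camera adjusted p = 1e-11, and adjusted p = 0.749 with an estimated correlation). Cdk1, a kinase that drives mitosis, stood at 39.2 CPM in females and 9.62 CPM in males (1.91 ± 0.28, adjusted p = 0.0621), and passed without either day 21 library. Of 10 complement genes, 0 were called over all genes and 7 were lower in females adjusted over the list alone (camera adjusted p = 6.76e-05, and adjusted p = 0.749 with an estimated correlation). C3, the central complement protein, stood at 135 CPM in females and 225 CPM in males (−0.81 ± 0.18, adjusted p = 0.137). The same fibroblasts of females had a median log2 change of −2.26 over the hemoglobin and erythroid genes.

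Over all genes, edgeR called 56 genes by sex in neutrophils (37 of them autosomal), 63 in B or plasma cells (49), 12 in erythroid cells (6), 15 in endothelial cells (8), 7 in macrophages or monocytes (1) and 18 in fibroblasts (12). The 1 autosomal gene in macrophages or monocytes was Klkb1 (1.12 ± 0.14, adjusted p = 0.0406), named after its value was seen, and its call was lost without any day 0, day 7 or day 21 library. DESeq2 called 65, 74, 15, 19, 11 and 188 genes in the same order of classes. Leaving out either library of a day takes that day out of the test by sex, and this moved the counts. The neutrophil count was 136 and 132 without the female and male day 0 library, 32 and 30 without the day 7 ones and 32 without either day 21 library. In endothelial cells it was 121 and 128 without the day 0 libraries, 27 and 24 without the day 3 ones and 7 without either day 7 library. In fibroblasts it was 1 without either day 0 library and 75 and 61 without the day 3 ones. In B or plasma cells it was 27 and 28 without the day 7 libraries and 21 and 32 without the day 21 ones. In erythroid cells it was 23 and 20 without the day 0 libraries, 5 without either day 3 library and 7 and 5 without the day 7 ones. Macrophages or monocytes had 12 and 11 without the day 3 libraries and 3 and 4 without the day 21 ones.

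The day 3 comparison asked which genes changed early after injury in both sexes. In macrophages or monocytes, Spp1 (osteopontin, a secreted matrix and signalling protein) rose from 25.1 to 5355 CPM (log2 change 8.07 ± 1.39, adjusted p = 0.0478), with 9290 CPM in the female and 1420 CPM in the male library. Arg1, the arginase of repair-type macrophages, stood at 796 and 154 CPM in the female and male day 3 libraries against a mean of 0.225 CPM at day 0 (adjusted p = 0.043). Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 27.4 to 308 CPM (3.48 ± 0.42, adjusted p = 0.0249), and Saa3, an acute-phase protein, rose from 0.662 to 64.0 CPM (6.52 ± 0.49, adjusted p = 0.00548). Of 16 recruited-monocyte and lipid-associated macrophage genes, 4 rose over all genes (Arg1, Fabp5, Gpnmb and Spp1), and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.593 with an estimated correlation). Of 20 inflammatory cytokines and chemokines, 2 rose over all genes (Saa3 and Ccl7), and 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00584, and adjusted p = 0.61 with an estimated correlation). Fxyd2, a regulator of the sodium pump, fell from 351 to 10.8 CPM (−5.21 ± 0.42, adjusted p = 0.00548), the only one of these calls kept with any 1 library left out. Neutrophil genes moved with these, since Wfdc21 rose (4.83 ± 0.73, adjusted p = 0.0424) and 8 of the neutrophil list rose adjusted over the list alone. In the C1qb-low monocyte cluster 5 alone, the change of Fabp5 turned to −0.40. With 1 library left out, the log2 change ran from 5.02 to 9.69 for Spp1 and from 2.81 to 4.05 for Gpnmb. Spp1, Arg1, Ccl7 and Wfdc21 lost the call without either day 0 or day 21 library, Fabp5 without either day 0 or the female day 21 library, and Gpnmb and Saa3 without either day 0 library.

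In endothelial cells at day 3, 2188 genes changed, 1170 of them upward, while DESeq2 called 1183. The class itself shifted, since its Plvap-high cluster 22 was 14.4% and 14.2% of the class in the female and male day 0 libraries and 32.3% and 30.9% at day 3. Hmox1 (ENSMUSG00000005413), which encodes heme oxygenase, an enzyme that breaks down heme, rose from 26.8 to 185 CPM (2.80 ± 0.15, adjusted p = 9.19e-06) and stayed high later. The cytokine gene Il6 rose from 6.76 to 46.9 CPM (2.68 ± 0.40, adjusted p = 0.00229) and the neutrophil-attracting chemokine Cxcl1 from 12.7 to 54.2 CPM (2.27 ± 0.40, adjusted p = 0.00426). The metal-binding protein gene Mt1 rose from 16.6 to 158 CPM (3.18 ± 0.58, adjusted p = 0.00486). Of 11 inflammatory cytokines and chemokines, 6 rose and 1 fell over all genes (camera adjusted p = 0.0113, and adjusted p = 0.593 with an estimated correlation). Of 17 matrix proteases and inhibitors, 7 rose, among them Plaur, the urokinase receptor (1.65 ± 0.17, adjusted p = 0.000551), Timp1, an inhibitor of matrix metalloproteinases (2.63 ± 0.34, adjusted p = 0.00145), and the membrane protease Mmp14 (1.94 ± 0.26, adjusted p = 0.00165). For the list, camera gave adjusted p = 0.0014, and adjusted p = 0.595 with an estimated correlation. Oxidative phosphorylation rose in 25 of 32 genes (camera adjusted p = 2.95e-10, and adjusted p = 0.618 with an estimated correlation) and proliferation in 12 of 20 (camera adjusted p = 1.62e-06, and adjusted p = 0.593 with an estimated correlation). Angiogenesis genes went both ways, with 4 of 18 up, among them Apln, a peptide of sprouting vessels (3.18 ± 0.45, adjusted p = 0.00185), and 6 down (camera adjusted p = 0.905). Bmp6, a bone morphogenetic protein made by endothelium, fell from 514 to 229 CPM (−1.18 ± 0.18, adjusted p = 0.00229), as did Ltbp1, which binds latent TGF-beta (−2.49 ± 0.23, adjusted p = 0.000296). Hemoglobin moved with these, and Hbb-bs fell from 8767 to 1266 CPM (−2.74 ± 0.55, adjusted p = 0.00759), with 6 of 7 listed genes lower. Few cells carried much of it, since 11 of 424 endothelial cells of the male day 0 library held 91.4% of their hemoglobin UMIs. Cells with under 100 such UMIs went from means of 6.88 and 14.6 in the female and male day 0 libraries to 3.035 and 9.82 at day 3. In endothelial cluster 4 alone, the change of Apln turned to −0.38, and Cxcl1 was called in neither cluster 4 nor cluster 22 alone. Without the female day 3 library the change was 1.22 for Cxcl1 and 2.45 for Apln, and without the male day 3 library it was 2.25 for Mt1 and 2.09 for Il6. Hbb-bs lost the call without the male day 0 library, and the count fell to 918 without the female day 0 library, 1268 without the male day 0 library and 772 without the female day 3 library.

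In fibroblasts at day 3, a part of the complement and cell-cycle genes rose (2 of 10 and 11 of 25). At the same time cluster 14, whose markers score higher for tendon than for fibroblasts, went from 63.1% and 51.9% of the class in the female and male day 0 libraries to 28.4% and 38.6% at day 3. C3 rose from 60.7 to 363 CPM (2.61 ± 0.26, adjusted p = 0.0259) and Cfb, complement factor B, from 4.69 to 31.5 CPM (2.84 ± 0.46, adjusted p = 0.0412). These were 2 of 10 complement genes, with 5 higher adjusted over the list alone (camera adjusted p = 0.000199, and adjusted p = 0.595 with an estimated correlation). Of 25 proliferation genes, 11 rose, among them Mki67, a marker of cycling cells, from 14.95 to 93.6 CPM (2.71 ± 0.36, adjusted p = 0.03). Among the 25, 24 were higher adjusted over the list alone (camera adjusted p = 3.92e-17, and adjusted p = 0.595 with an estimated correlation). The monocyte-attracting chemokine Ccl7 rose from 5.02 to 141 CPM (4.56 ± 0.68, adjusted p = 0.0361). Bglap2, an osteocalcin gene, fell from 205 to 38.8 CPM (−2.45 ± 0.31, adjusted p = 0.03), and was called in neither cluster 10 nor cluster 14 alone. It was the only one of 15 bone genes called, with 7 lower adjusted over the list alone (camera adjusted p = 3.18e-06, and adjusted p = 0.595 with an estimated correlation). Of 21 BMP and TGF-beta genes, 2 fell, Bmp6 (−1.72 ± 0.22, adjusted p = 0.03) and Tgfb1 (−1.16 ± 0.19, adjusted p = 0.0406), with camera adjusted p = 0.00132, and adjusted p = 0.593 with an estimated correlation. The count was 105 genes, 85 up and 20 down, while DESeq2 called 380, with 228 up and 152 down. The edgeR count depended on which library was left out. It was 0 without either day 0 library, 7 without the female day 3 library, 1029 without the male day 3 library and 181 to 189 without any 1 of the day 7 and day 21 libraries. All of these named fibroblast genes lost the call without either day 0 library, and all but C3 also without the female day 3 library.

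In neutrophils at day 3, 2384 genes changed, 1363 of them upward, while DESeq2 called 1680. Ifitm1 (ENSMUSG00000025491), an interferon-induced membrane protein, rose from 37.1 to 439 CPM (3.55 ± 0.10, adjusted p = 1.42e-09), and Wfdc17, a secreted antiprotease-like protein, from 12.8 to 382 CPM (5.04 ± 0.28, adjusted p = 1.63e-06). Oxidative phosphorylation rose in 27 of 32 genes, by 0.79 ± 0.09 for Atp5j (adjusted p = 0.000212), with camera adjusted p = 1.16e-12, and adjusted p = 0.593 with an estimated correlation. Proliferation rose in 18 of 25 genes (camera adjusted p = 2.92e-07, and adjusted p = 0.688 with an estimated correlation). The mix of clusters shifted as well. Cluster 9, led by Fcnb and Camp, went from 16.4% and 11.8% of the class in the female and male day 0 libraries to 17.7% and 23.5% at day 3. Cluster 0 went from 29.2% and 28.7% to 19.4% and 25.1%. The lists were not tested within clusters, so a part of these rises may come from the shift. Of 22 dissociation-stress and immediate-early genes, 15 fell. Among them were Atf3 from 86.6 to 33.6 CPM (−1.39 ± 0.13, adjusted p = 6.85e-05), Dusp1 (−1.31 ± 0.15, adjusted p = 0.000238) and Fos (−1.59 ± 0.24, adjusted p = 0.00105). Over this list camera gave adjusted p = 1.32e-06, and adjusted p = 0.61 with an estimated correlation. The list is named for the stress of cell dissociation, and a difference in digestion between libraries was not tested. Thbs1, the matrix protein thrombospondin, fell from 1020 to 333 CPM (−1.60 ± 0.26, adjusted p = 0.00137). The count was 1560, 1308, 1481 and 1555 without the female day 0, male day 0, female day 3 and male day 3 library. All of these named neutrophil genes passed with any 1 library left out.

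The other counts at day 3 were lower: 79 genes in macrophages or monocytes (44 up), 29 in erythroid cells (all up) and 2 in B or plasma cells (both up), with DESeq2 counts of 326, 47 and 97. Of the 2 in B or plasma cells 1 was Apoe, a lipid carrier of macrophages (54.0 to 194 CPM, 1.86 ± 0.17, adjusted p = 0.000667), lost without the male day 0 library. The other was Klkb1 (1.36 ± 0.18, adjusted p = 0.0216), lost without any day 0 or day 7 library. In erythroid cells 7 of 14 neutrophil genes rose, among them S100a8, a calcium-binding protein of neutrophils (232 to 1319 CPM, 2.51 ± 0.24, adjusted p = 0.00569), with camera adjusted p = 1.53e-14, and adjusted p = 0.593 with an estimated correlation. Few cells carried this, since 4 of 330 and 13 of 1070 erythroid cells of the female and male day 3 libraries held 89.5% and 68.3% of the S100a8 and S100a9 UMIs. S100a8 lost the call without the female day 3 library, which left 0 genes in erythroid cells, against 15 without the female day 0 library. The macrophage or monocyte count was 2 and 1 without the female and male day 0 library and 26 and 40 without the female and male day 21 library. It was 53 without the female day 7 library, which stays within 1.5 times, and 1891 without the male day 3 library. The B or plasma count was 571 without the male day 3 library, 11 without the female day 3 library, 5 and 0 without the female and male day 0 library, 1 without either day 7 library and 9 and 13 without the day 21 ones.

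**Figure D2:**
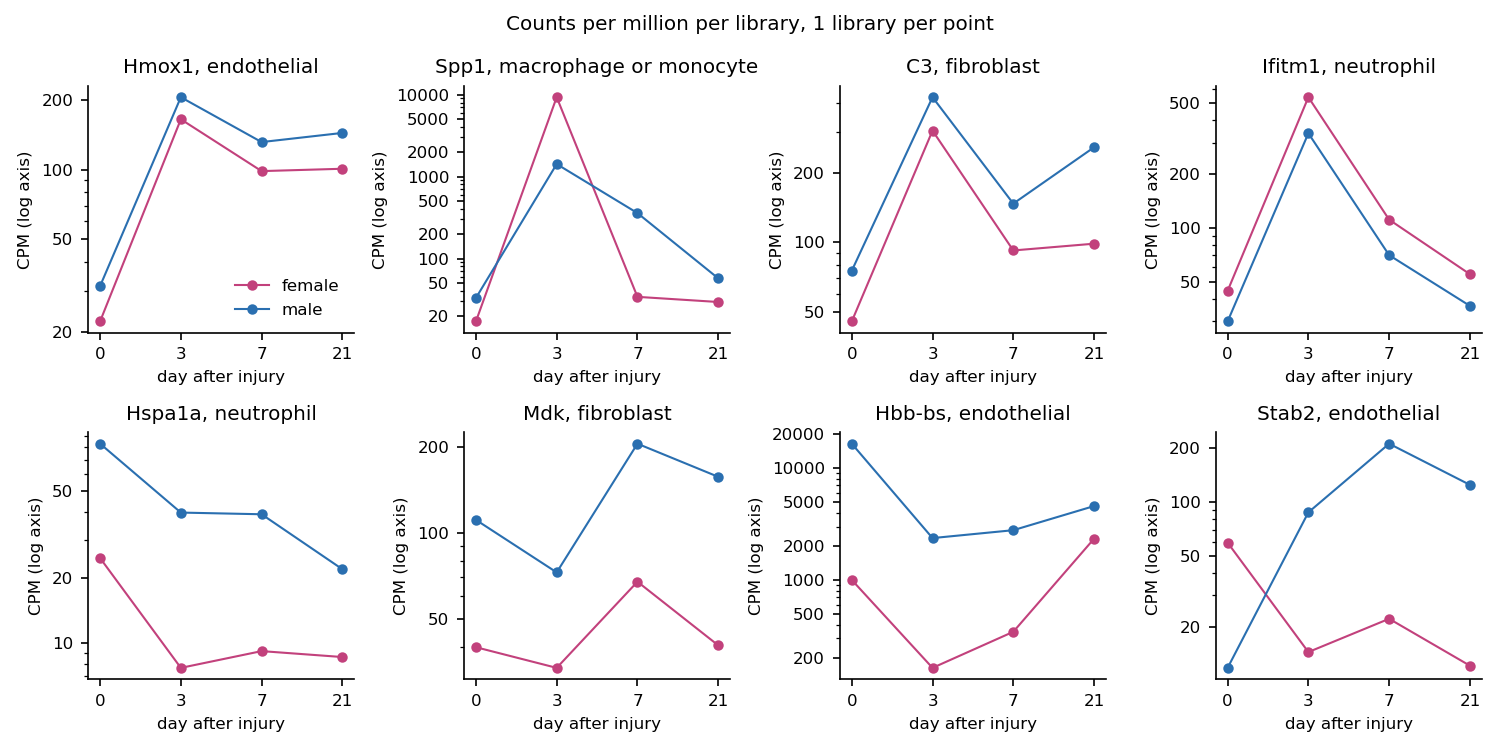
CPM (log axis) of 8 gene and class pairs by day after injury, 1 point per library, females and males in separate colours. Hmox1 in endothelial cells rose from a mean of 26.8 CPM at day 0 to 185 CPM at day 3, and Hspa1a in neutrophils was lower in the female library on all 4 days.

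The day 7 comparison asked which changes were present 1 week after injury. In neutrophils, at their largest share, 2537 genes were called, 1795 upward, and DESeq2 called 940. Of the 1718 edgeR calls of at least 2-fold, 1677 were up and 41 down. Gm10800, Gm10801 and Klkb1, weighed below as material from outside cells, rose in the same class. Their UMIs per 100 neutrophils went from 240 and 157 in the female and male day 0 libraries to 1002 and 547 at day 7. How much of the count comes from such material was not tested. The class carried more Il1b, an inflammatory cytokine, at 476 against 244 CPM (0.96 ± 0.18, adjusted p = 0.00355). As the mix of clusters 1 and 2 shifted as given above, Il1b was fitted within clusters. It was called in clusters 2 and 7 alone (0.70 and 1.34) but not in clusters 0 and 9 alone. Cluster 1, the one that grew, had 26 cells in the male day 0 library, under the 30 needed, and was not fitted. These fits therefore cannot say whether the growth of cluster 1 made the rise. At resolution 2.0, neutrophils led by Ltf and Ly6g were split by day as well. Cluster 8 of that clustering held 901 and 523 cells in the female and male day 7 libraries and 2 to 69 elsewhere. Whether the day 7 libraries differ as a whole from the others, apart from injury, was not tested. The class carried less of the heat-shock chaperone Hsp90aa1, at 205 against 346 CPM (−0.75 ± 0.09, adjusted p = 0.000282). Transcripts of other tissues rose in the same cells: 8 of 15 skeletal muscle genes, among them Ckm, a muscle creatine kinase (4.31 to 20.0 CPM, 2.24 ± 0.41, adjusted p = 0.0039). So did 4 of 10 cartilage matrix genes, among them the cartilage collagen Col2a1 (1.58 to 7.55 CPM, 2.25 ± 0.39, adjusted p = 0.00294). The muscle list had camera adjusted p = 0.00163, and adjusted p = 0.748 with an estimated correlation, and the cartilage list camera adjusted p = 0.0434, and adjusted p = 0.701 with an estimated correlation. Gm10800 rose from 153 to 860 CPM (2.38 ± 0.23, adjusted p = 8.49e-05) and the giant muscle protein gene Ttn from 24.5 to 117 CPM (2.32 ± 0.53, adjusted p = 0.0116). Hbb-bs fell from 1623 to 479 CPM (−1.76 ± 0.46, adjusted p = 0.02). Ttn and Hbb-bs lost the call without the female day 0 or male day 7 library and Ckm without the female day 0 library. The count was 576 without the female day 0 library, 825 without the female day 7 library and 1182 without the male day 7 library.

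In endothelial cells at day 7, Hmox1 stood at 115 against 26.8 CPM (2.10 ± 0.16, adjusted p = 0.000271), a call kept with any 1 library left out. Plaur (1.24 ± 0.18, adjusted p = 0.0192) and the chemokine Ccl2 (0.741 to 16.1 CPM, 4.37 ± 0.82, adjusted p = 0.0403) were still higher than at day 0, and Bmp6 was still lower (−1.09 ± 0.18, adjusted p = 0.0208). Ccl2 and Plaur lost the call without any day 0 or day 7 library, and Bmp6 without the female day 0 or either day 7 library. Of 32 oxidative phosphorylation genes, 0 were called over all genes and 21 were higher adjusted over the list alone (camera adjusted p = 5.05e-07, and adjusted p = 0.748 with an estimated correlation). The count was 164 genes, 111 up, by edgeR and 322 by DESeq2. It was 1 without either day 7 library, 96 and 21 without the female and male day 0 library, 628 and 536 without the day 3 ones and 43 and 49 without the day 21 ones.

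B or plasma and erythroid cells held more neutrophil transcripts at day 7, most of them in few cells. In erythroid cells 12 of 14 neutrophil genes rose, among them S100a8 (232 to 3644 CPM, 3.89 ± 0.26, adjusted p = 0.000216) and Wfdc21 (6.91 to 165 CPM, 4.39 ± 0.34, adjusted p = 0.000302). Both passed with any 1 library left out (list camera adjusted p = 4.03e-17, and adjusted p = 0.701 with an estimated correlation). Of the S100a8 and S100a9 UMIs in erythroid cells, 93.8% and 89.1% lay in 15 of 211 and 15 of 501 cells of the female and male day 7 libraries, and the other cells held means of 6.28 and 3.58, against 4.91 and 2.82 at day 0. For B or plasma cells, 5 and 12 cells held 77.8% and 90.3%. In B or plasma cells 8 of 14 rose, among them Ngp, a neutrophil granule protein (2.68 ± 0.59, adjusted p = 0.0266), which lost the call without any day 0 or day 7 library and turned to −0.08 with doublets kept. The list had camera adjusted p = 2.73e-06, and adjusted p = 0.701 with an estimated correlation. All 7 hemoglobin and erythroid genes fell in B or plasma cells, Hbb-bs from 10150 to 589 CPM (−4.08 ± 0.29, adjusted p = 3.99e-05), with camera adjusted p = 7.4e-09, and adjusted p = 0.701 with an estimated correlation. At day 0, 13 and 17 cells held 92.0% and 89.1% of the hemoglobin UMIs of the class in the female and male library, against 2 and 0 such cells at day 7. The other cells went from means of 6.63 and 14.7 to 1.68 and 4.77. Dissociation-stress genes fell in 11 of 22 in B or plasma cells (camera adjusted p = 2.07e-08, and adjusted p = 0.701 with an estimated correlation). Among them Hspa1a changed by −1.54 ± 0.20 in log2 (adjusted p = 0.00215), a call lost without the female day 0 or female day 7 library. The counts were 524 in B or plasma cells and 210 in erythroid cells by edgeR and 267 and 203 by DESeq2. Without the day 7 libraries in turn they were 51 and 50 in B or plasma cells and 74 and 64 in erythroid cells, and without the female day 0 library 31 and 79. Without the male day 0 library they were 245 and 91, without the day 3 libraries 960 and 912 in B or plasma cells and 124 and 140 in erythroid cells (the latter within 1.5 times), and without the day 21 ones 277 and 284 in B or plasma cells.

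Macrophages or monocytes and fibroblasts changed in few genes at day 7 by this test. In macrophages or monocytes 3 genes rose, Gm10801 (64.3 to 373 CPM, 2.47 ± 0.27, adjusted p = 0.0491), Klkb1 (1.94 ± 0.20, adjusted p = 0.044) and Gm21738 (2.52 ± 0.26, adjusted p = 0.044), the last pair named after their values were seen. Each lost the call without any day 0, day 7 or day 21 library. The count was 72 and 57 without the day 3 libraries, 1 without the female day 0 or male day 7 library and 0 without the male day 0, female day 7 or either day 21 library. DESeq2 called 32 genes there, and 889 had an unadjusted p under 0.05. In fibroblasts edgeR called 0 genes, with 1101 at an unadjusted p under 0.05, and DESeq2 called 23. It called 1, 3 and 4 without the female day 3, male day 3 and female day 7 library. Inflammatory genes in fibroblasts were higher in 5 of the list adjusted over the list alone (camera adjusted p = 0.000234, and adjusted p = 0.701 with an estimated correlation).

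The day 21 comparison asked what remained 3 weeks after injury, and few genes passed. In endothelial cells Hmox1 was the single gene called, at 122 against 26.8 CPM (2.19 ± 0.15, adjusted p = 0.000147), and it passed with any 1 library left out. In neutrophils Hspa1a stood at 15.2 against 53.9 CPM (−1.79 ± 0.18, adjusted p = 0.00281), and Tnfaip6, a hyaluronan-binding protein induced by inflammation, at 83.3 against 193 CPM (−1.22 ± 0.12, adjusted p = 0.00281), both lost without the male day 21 library. Dissociation-stress genes were lower in 3 of 22 in neutrophils (Hspa1a, Hsp90aa1 and Jun). Adjusted over the list alone, 9 were lower and 1 higher (camera adjusted p = 2.85e-06, and adjusted p = 0.869 with an estimated correlation). In B or plasma cells Apoe (54.0 to 131 CPM, 1.31 ± 0.16, adjusted p = 0.0293) and H2-DMb2 (45.5 to 102 CPM, 1.21 ± 0.19, adjusted p = 0.0393) rose and Gadd45g, a growth-arrest gene, fell (−1.50 ± 0.25, adjusted p = 0.0406). All 3 lost the call without any day 0, day 7 or day 21 library, and with doublets kept the fall of Retnlg, a secreted neutrophil protein (−1.75 ± 0.30, adjusted p = 0.0423), turned to 0.12. All 9 MHC class II genes in B or plasma cells were higher adjusted over the list alone (camera adjusted p = 9.11e-09, and adjusted p = 0.869 with an estimated correlation), while the MHC-rich cluster 6 went from 32.0% and 25.8% of the class at day 0 to 65.4% and 51.7% at day 21. In fibroblasts 0 of 10 complement genes were called over all genes and 6 were higher adjusted over the list alone (camera adjusted p = 7.97e-06, and adjusted p = 0.869 with an estimated correlation).

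At day 21 edgeR called 7 genes in neutrophils, 28 in B or plasma cells, 1 in endothelial cells and 0 in erythroid cells, macrophages or monocytes and fibroblasts. In the last 3 classes 336, 839 and 962 genes had an unadjusted p under 0.05, and DESeq2 called 0, 41 and 31. These counts moved with the library left out. In B or plasma cells the count was 176 and 170 without the day 3 libraries, 2 and 7 without the female and male day 0 library, 1 without the female day 21 library and 0 without the male day 21 or either day 7 library. In neutrophils it was 48 without either day 3 library, 31 and 27 without the day 7 ones, 11 and 14 without the day 0 ones, 3 without the female day 21 and 0 without the male day 21 library. In macrophages or monocytes it was 108 and 104 without the day 3 libraries, 5 without the female day 0 library and 1 without either day 7 library. In fibroblasts it was 23 and 19 without the day 3 libraries, 13 without the female day 21 library and 1 without either day 7 library. Erythroid cells had 17 without the female day 0 library, and endothelial cells 56 and 4 without the female and male day 0 library and 16 without either day 3 library.

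The last test asked whether the response to injury, days 3, 7 and 21 together against day 0, differed between the sexes. In endothelial cells 5 genes had a lower response in females than in males. Stab2 (ENSMUSG00000035459), a scavenger receptor of sinusoidal endothelium, went from 59.1 CPM in the female day 0 library to 12.1 to 22.1 CPM in the injured female libraries. In the male ones it went from 11.8 to 87.4, 212 and 125 CPM (difference of log2 changes −5.37 ± 0.36, adjusted p = 2.46e-05). Mrc1 (ENSMUSG00000026712), the mannose receptor, went from 23.5 to 7.37 to 9.78 CPM in females and from 4.62 to 51.3 to 86.1 CPM in males (−5.21 ± 0.44, adjusted p = 0.00018). Of the Stab2 and Mrc1 UMIs of the class, 93% lay in 77 of 3751 cells, with 11 of these cells in the female and 3 in the male day 0 library. Rgs4, Ubd and Adgrg6, named after their values were seen, were called the same way. In erythroid cells 1 gene was called. In neutrophils Ifi27l2a, an interferon-induced gene, had a difference of 2.09 ± 0.27 (adjusted p = 0.118), and in macrophages or monocytes the MHC class II gene H2-Eb1 had −2.88 ± 0.27 (adjusted p = 0.222), neither past the threshold.

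For the interaction edgeR called 0 genes in neutrophils, B or plasma cells, macrophages or monocytes and fibroblasts, with 865, 541, 371 and 224 at an unadjusted p under 0.05 and 1, 1, 4 and 1 called by DESeq2. With the interaction design's own low-count filter the counts were 1 in neutrophils and in B or plasma cells, 2 in erythroid cells and 11 in endothelial cells. Each day 0 group has 1 library per sex, so the interaction rests on those 2 libraries, and it cannot be estimated without either. Both are fitted exactly, so the p values and errors of the interaction hold no spread between day 0 libraries. The endothelial count was 67 and 123 without the female and male day 3 library and 25 and 24 without the day 21 ones. The erythroid count was 0 without the female day 3 library, 5 and 31 without the male day 3 and male day 7 libraries and 644 and 549 without the female and male day 21 library. The neutrophil count was 41 and 34 without the day 3 libraries, 8 and 19 without the day 7 ones and 1 without the female day 21 library. B or plasma cells had 64 and 60 without the day 3 libraries and 1 without the male day 7 library. There were 3 without either day 3 and 2 without either day 7 library in macrophages or monocytes. Ifi27l2a passed without any 1 of the day 3, day 7 and female day 21 libraries, and H2-Eb1 without either day 3 library. Stab2, Mrc1 and Ubd passed in all 6 fits that left out an injured library, and Rgs4 and Adgrg6 lost the call without either day 7 library.

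At each single day the sexes could be compared only as 1 library against 1, with no replicate check. In fibroblasts the median log2 ratio of female over male CPM over 25 proliferation genes was 0.61 at day 0, 1.35 at day 3, 2.28 at day 7 and 0.24 at day 21, at or above the 98.8th percentile of random lists on each day. Dissociation-stress and immediate-early genes in the same fibroblasts had −0.28, −0.27, −0.78 and −0.58, at or below the 1.3th percentile. In B or plasma cells the median over 9 MHC class II genes was 0.48, 1.02, 0.55 and 0.32, at or above the 99.99th percentile, with more of the class in the MHC-rich cluster 6 in the female library on each day. Over 32 oxidative phosphorylation genes in endothelial cells it was 0.12, 0.49, 0.20 and 0.43, at or above the 98.97th percentile. Hemoglobin and erythroid genes in endothelial cells had medians of −3.43, −2.76, −1.98 and −1.20, below all random lists, and neutrophil genes had 1.44, 0.76, 0.21 and 2.89 in B or plasma cells and 0.43, 0.68, 1.19 and 0.60 in erythroid cells. Of 151 pairs of list and class, 62, 81, 67 and 65 lay outside the central 95% of random lists at days 0, 3, 7 and 21, against 7.6 by chance if genes were independent. These percentiles describe the 2 libraries of a day and not the sexes.

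**Figure D3:**
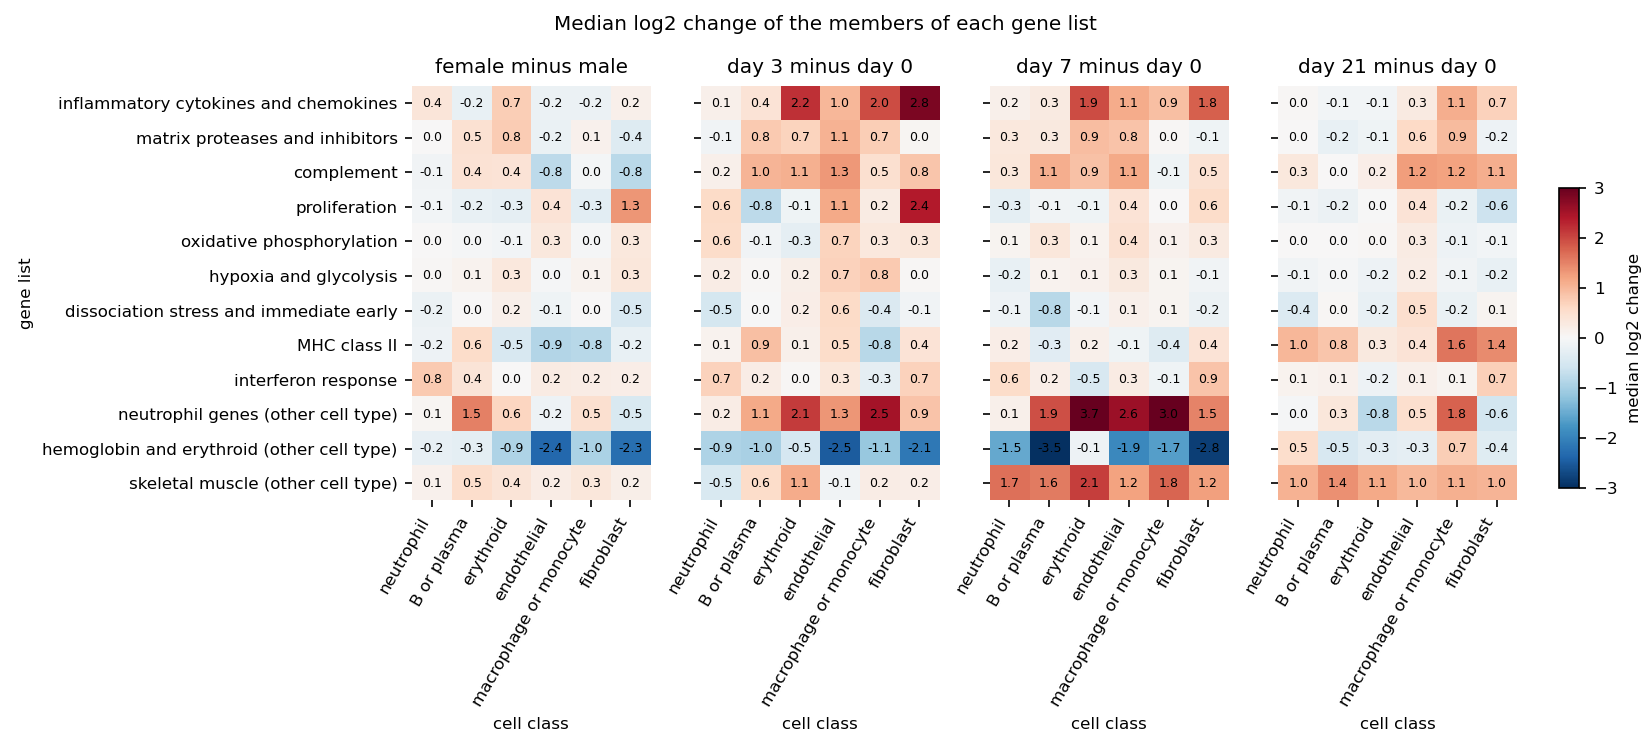
Median log2 change of the measured members of 12 gene lists (vertical axis) in the 6 main cell classes (horizontal axis) for females minus males and for days 3, 7 and 21 minus day 0, written in each cell and coloured from −3 to 3. The hemoglobin median in endothelial cells was −2.35 by sex, and no list passed with an estimated correlation, a test with 3 residual degrees of freedom.

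Over all lists and classes, camera with the preset correlation called 43 of 151 pairs by sex, 59 at day 3, 55 at day 7 and 37 at day 21. With an estimated correlation 0 were called in each contrast, with 3, 9, 6 and 5 at an unadjusted p under 0.05 and smallest adjusted p = 0.749, 0.593, 0.701 and 0.869 with an estimated correlation. With an estimated correlation the test has 3 residual degrees of freedom, which makes a call over 151 pairs unlikely, so its 0 calls say little about any list. By fry, 1, 3, 0 and 0 pairs were called. Few genes of the synovial lining, nerve and sex hormone lists were called. Of the synovial lining and lubricant genes 1 rose and 4 fell at day 3 over all classes and 0 were called in the other contrasts. Of the nociception and nerve growth genes 2 rose and 3 fell at day 3 and 5 rose at day 7. The low-UMI unnamed cluster 3, led by the neuropeptide gene Calca, was 13.7% and 8.67% of the female and male day 7 libraries. At day 0 it was 2.39% and 3.01%. Whether stray RNA of such barcodes made the rise at day 7 was not tested. Of the sex hormone receptors and targets 4 rose and 1 fell at day 3, among them Hsd11b1 in fibroblasts, which activates glucocorticoids (2.02 ± 0.34, adjusted p = 0.0451, lost without any day 0 or day 3 library), and 0 were called by sex. Skeletal muscle genes had a positive camera call in all 6 classes at day 7 and at day 21, with 13 and 0 genes called, while the smallest value over the 6 classes was adjusted p = 0.701 at day 7 and adjusted p = 0.869 at day 21 with an estimated correlation.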

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

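The test of slopes was set before its result was seen, while the tests of UMIs per cell, of hemoglobin, of single clusters and of a subset of cells were chosen after the results were seen. The regroupings of the libraries were planned, but counting autosomal genes and distinct fits alone was chosen after the results were seen.

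In endothelial cells, Stab2 and Mrc1 stood out because the response to injury differed between the sexes by a test of the difference itself, by −5.37 ± 0.36 (adjusted p = 2.46e-05) and −5.21 ± 0.44 (adjusted p = 0.00018) in log2. A different mix of the 2 endothelial clusters in the 8 libraries is argued against, since within cluster 22 alone the mean difference of the pair was −5.11, with adjusted p = 0.000214 for each gene. The criterion written down asked for this in both clusters. In cluster 4 Mrc1 was not measured and Stab2 had −0.52 ± 1.66, so the pattern lay in cluster 22 and nothing can be said of cluster 4. A smaller subset goes with the pattern. At resolution 2.0, a cluster of 77 of the 3751 cells held 93% of the UMIs of the 2 genes, with 11 cells in the female and 3 in the male day 0 library and 6 to 7 and 11 to 16 in the injured ones. The difference of log2 changes was −2.82 for its share of the class and −2.53 for UMIs per cell within it, so a shift in the share of this subset is consistent with part of the pattern. The clustering itself uses such genes, and 3 cells make a weak baseline. The fit matches both day 0 libraries exactly, so the errors and adjusted p values above hold no spread of that baseline. Both day 0 libraries carry this difference, with no replicate of either, so a difference between those 2 libraries other than sex stays open beside a biological difference by sex, which was not tested in other animals.

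Other genes whose response to injury differed by sex in endothelial cells were Rgs4 (−4.76 ± 0.61, adjusted p = 0.0108), Ubd (−5.71 ± 0.73, adjusted p = 0.0108) and Adgrg6 (−4.22 ± 0.61, adjusted p = 0.0288). Ubd was among the leading genes of the same cluster of 77 cells that held most Stab2 and Mrc1 UMIs, so it need not be a separate pattern. Whether Rgs4 and Adgrg6 lay in that cluster was not tested.

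Gm10800, Gm10801 and Klkb1 were higher in female libraries and at day 7 across the 6 main classes. Material outside cells, taken up by every droplet alike, would give each class about as many UMIs per cell whatever its RNA content, and within libraries the slope of the 3 genes' UMIs per cell on total UMIs per cell had a median of −0.014, with all 8 slopes from −0.30 to 0.10, so the pattern is consistent with such material. A lower number of UMIs per cell in female libraries is argued against, since UMIs per cell of the 3 genes, not divided by the total, were higher in females in 24 of 24 comparisons with a median log2 ratio of 1.28. The unnamed clusters 3 and 18, with medians of 646 and 1803 UMIs, also had Gm10800 and Gm10801 among their leading genes. At days 0, 3, 7 and 21, cluster 3 was 2.39%, 11.2%, 13.7% and 7.01% of the female libraries. In the male ones it was 3.01%, 1.58%, 8.67% and 0.553%. Cluster 18 was higher in the female library at days 3 and 21 only. Both count among the kept cells of every share. Where such material comes from, and any difference by sex behind it, was not tested.

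Hemoglobin RNA was lower in female than in male endothelial cells. Among cells with under 100 hemoglobin UMIs, endothelial cells held 1.04 times as many per cell as neutrophils of the same library (0.954 to 1.09 over 8 libraries), which is consistent with free hemoglobin RNA in each library. In addition, 81% of the hemoglobin UMIs of the class lay in 36 of 3751 cells with 100 or more, which may hold the contents of a red cell. At days 0, 3, 7 and 21 these were 3, 1, 3 and 6 cells in females and 11, 2, 2 and 8 in males. The hemoglobin and erythroid list had a median change of −2.35 in endothelial cells and −2.26 in fibroblasts. It had −0.24 in neutrophils, −0.28 in B or plasma cells and −0.95 in macrophages or monocytes. Free RNA shared by all classes would not by itself give such unlike values. A different mix of endothelial clusters in the sexes is argued against, since the list had a median change of −2.10 in the cluster closest to 0 and −3.27 in the other. Both remaining explanations concern RNA from outside endothelial cells, and a difference by sex in the blood left in the joints stays open, untested.

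Shares of cells in classes that no gene comparison used stood out in 9 cases, where the lower 95% limit of an injured library lay above the upper 95% limits of both day 0 libraries. Chondrocytes were 1.21% (95% interval 0.970% to 1.48%) of the female day 7 library, against 0.317% and 0.0760% at day 0. This depends on the clustering, since at resolution 2.0 the main chondrocyte cluster had 54 of 5358 cells in the female day 0 and 95 of 7468 in the female day 7 library. Epithelial cells were 7.49% of the male day 3, 2.68% of the female day 21 and 4.44% of the male day 21 library, against 0 of 5358 cells, which allows up to 0.0690%, and 1.27% at day 0. Hematopoietic progenitors were 7.11% of the male day 3 library, against 3.51% and 3.13%. Osteoblasts were 1.21% of the female day 21 library, against 0.485% and 0.171%. Schwann cells were 2.34% of the female day 3, 1.79% of the male day 3 and 1.79% of the female day 21 library, against 0.989% and 0.379%. Outside these cases, injured libraries held 0.125% to 0.5% chondrocytes, 2.39% to 3.49% hematopoietic progenitors, 0.1% to 0.344% osteoblasts and 0.295% to 0.548% Schwann cells. Epithelial cells there were 0.15% (female day 3), 0.281% (female day 7) and 0 of 6392 cells (male day 7), under the male day 0 value. None of these classes passed the test of shares.

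Whether other groupings of the libraries give as many autosomal genes was counted over the 20 splits of the 8 libraries into 4 and 4 that differ once the day term is fitted. These are too few for a share under 0.05. As many autosomal genes as the split by sex came from 1 split in neutrophils (37, highest other 19), 1 in B or plasma cells (49, highest other 13), 1 in fibroblasts (12, highest other 4), 2 in erythroid cells (6, highest other 1135), 3 in endothelial cells (8, highest other 55) and 4 in macrophages or monocytes (1, highest other 2), the split by sex included. The erythroid split with 1135 genes sets females against males at days 3 and 7 alone. That grouping follows sex on those days, but the mix of clusters did too. Erythroid cluster 21 was 54.2% and 38.4% of the class in females on those days and 14.9% and 9.98% in males. Its barcodes had a median of 1212 UMIs, and 22.2% of them were removed as doublets. Of the female cells of the class, 121 of 330 and 105 of 211 held 100 or more hemoglobin UMIs at days 3 and 7. In males 883 of 1070 and 450 of 501 did, so many female cells are weakly supported as erythroid. The endothelial split with 55 sets the female day 0 with the 3 injured male libraries, which is the structure of the interaction.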

How the results depend on the processing

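Chosen after seeing the data were the fits of single clusters, the fits without the day 7 libraries, the filter of the interaction design and the leaving out of injured libraries in the interaction fit. For 139 results on single genes, 1800 values under alternatives kept their direction and side of the threshold, 579 lost the call, 47 gained it, 9 reversed and 1 that was not called changed sign (C3 by sex in fibroblast cluster 14, 0.48). Of 127 called results among them, 80 lost the call in at least 1 fit without a library, and the fold change of 38 moved more than 1.5 times in 1 or more of these fits. Counts of genes depended on most choices, and where no cause is named the cause was not tested. No analysis paired by animal applied, because each library is of left joints of 1 sex at 1 day and libraries therefore share no animal. Resolution 2.0 added classes of osteoclasts, satellite cells and tendon cells, whose shares have no value at resolution 1.0 to compare with. At 2 libraries per day and 1 per sex and day, many 2-fold changes are missed at day 3, where simulated data recovered 13% (fibroblasts) to 60% (neutrophils) of them.

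The reversed values were −0.45 for Ccl4 by sex in neutrophil cluster 0, −0.29 for Ltf and −0.071 for Lyz2 by sex in B or plasma cells with doublets kept, −0.86 for Ltf and −0.44 for Lcn2 in cluster 6, −0.38 for Apln at day 3 in endothelial cluster 4, −0.40 for Fabp5 at day 3 in monocyte cluster 5, and, with doublets kept, −0.079 for Ngp at day 7 and 0.12 for Retnlg at day 21 in B or plasma cells.

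In the counts that follow, classes are neutrophils, B or plasma cells, erythroid cells, endothelial cells, macrophages or monocytes and fibroblasts, in that order unless named. DESeq2's Wald test gave, by sex, 11 in macrophages or monocytes and 188 in fibroblasts, and at day 3, 97 in B or plasma, 47 in erythroid, 1183 in endothelial, 326 in macrophages or monocytes and 380 in fibroblasts. At day 7 it gave 940 in neutrophils, 267 in B or plasma, 322 in endothelial, 32 in macrophages or monocytes and 23 in fibroblasts, and at day 21, 29, 22, 41 and 31 in neutrophils, endothelial cells, macrophages or monocytes and fibroblasts. Its interaction counts were 1 in neutrophils, 1 in B or plasma cells, 0 in erythroid cells, 4 in macrophages or monocytes and 1 in fibroblasts.

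Without a low-count filter, which adds genes near 0 counts, the counts by sex were 456, 423, 491, 236, 155 and 898. At day 3 they were 780, 343, 1362 and 1376 in B or plasma, erythroid, macrophages or monocytes and fibroblasts, at day 7 they were 4044, 1418, 880, 927, 377 and 368, at day 21 they were 188, 333, 123, 170, 365 and 435, and for the interaction 70, 51, 114, 106, 47 and 25. The filter of the interaction design gave 1, 1, 2 and 11 for the first 4 classes. Stricter cells gave 11 in neutrophils at day 21 and 5 in B or plasma cells at day 3. Classes from Leiden resolution 2.0 gave 21 in neutrophils at day 21, 6, 1 and 14 in erythroid cells by sex, at day 3 and at day 7, and 184 and 49 in macrophages or monocytes and fibroblasts at day 3. With doublets kept, B or plasma cells gave 37 by sex, 14 at day 3 and 1 at day 21, erythroid cells 5, 0 and 42 by sex, at day 3 and at day 7, endothelial cells 50 at day 7, macrophages or monocytes 16 and 0 at days 3 and 7, and fibroblasts 1 at day 3. DESeq2 size factors gave 0 for the erythroid interaction and 109 in endothelial cells at day 7.

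Without the day term the counts by sex were 6, 6, 5 and 7 in the first 4 classes and 7 in fibroblasts. Without X and Y genes they were 28, 34, 0, 6, 0 and 11. The adjustment then runs without the strongest genes. Without the sex term, neutrophils gave 1667 at day 7 and 0 at day 21, B or plasma cells 0, 25 and 0 at days 3, 7 and 21, erythroid cells 0 and 1 at days 3 and 7, endothelial cells 1362 and 3 at days 3 and 7, macrophages or monocytes 0 at day 7 and fibroblasts 1 at day 3. Without the day 7 libraries, counts by sex were 22, 21, 4 and 7 in the first 4 classes, with 28 in neutrophils at day 21, 1 and 0 in B or plasma cells at days 3 and 21, 13 in erythroid cells at day 3, 33 and 1 in macrophages or monocytes and 172 and 1 in fibroblasts at days 3 and 21.

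Single clusters gave fewer or more genes, with fewer cells. Neutrophil cluster 0 gave 1013, 547 and 20 at days 3, 7 and 21, cluster 2 gave 16 by sex and 875 and 173 at days 3 and 7, cluster 7 gave 15 by sex and 1120, 367 and 3 at days 3, 7 and 21, and cluster 9 gave 20 by sex and 612 and 20 at days 3 and 7. B cell cluster 6 gave 32 by sex and 9 and 8 at days 3 and 21, and cluster 8 of the same class gave 129 by sex and 12, 121 and 1 at days 3, 7 and 21. Erythroid cluster 11 gave 9 at day 7, and cluster 21 gave 23 by sex and 3, 90 and 1 at days 3, 7 and 21. Endothelial cluster 22 gave 463, 0 and 0 and cluster 4 gave 872, 421 and 6 at days 3, 7 and 21. Macrophage cluster 15 gave 307 at day 3, and monocyte cluster 5 gave 31 by sex and 592, 110 and 9 at days 3, 7 and 21. Fibroblast cluster 10 gave 39 at day 3, and cluster 14 gave 15 and 7 at days 3 and 7. Of the gene lists called by sex and at days 3, 7 and 21, 0, 0, 0 and 0 were called with an estimated correlation and 1, 3, 0 and 0 by fry.

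With 1 library left out in turn, the counts by sex ran from 30 to 136, 21 to 77, 5 to 23, 7 to 128, 3 to 12 and 1 to 75. At day 3 they ran from 1308 to 2319, 0 to 571, 0 to 32, 772 to 1945, 1 to 1891 and 0 to 1029. At day 7 they ran from 576 to 3332, 31 to 960, 64 to 147, 1 to 628, 0 to 72 and 0 to 4, and at day 21 from 0 to 48, 0 to 176, 0 to 17, 1 to 56, 0 to 108 and 0 to 23. For the interaction they ran from 0 to 41, 0 to 64, 0 to 644, 5 to 123, 0 to 3 and 0 to 0. Called class shares ran from 0 to 1 by sex, 0 to 2 at day 3, 0 to 5 at day 7 and 0 to 1 at day 21.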

Other observations

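The fit within single clusters and the test of a shift between clusters were chosen after the day 3 results were seen.

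Genes at day 3 in the macrophage or monocyte class changed while the class itself shifted, since its C1qb-high cluster 15 grew from 16.1% and 19.1% of the class at day 0 to 78.7% and 32.9% at day 3 in the female and male library. The hypothesis that this shift alone made the calls was tested by refitting each cluster by itself. Over the called genes, the change within a cluster was a median of 0.843 of the change in the class in cluster 5 (58 of 69 genes called within it) and 1.09 in cluster 15 (35 of 60), where a pure shift needs values near 0, so a shift between these 2 clusters is argued against as the whole source. A shift between subsets inside cluster 15 stays open. At resolution 2.0 the C1qb-high cells were in 2 clusters, 1 of them led by Arg1 and Spp1 with 0 and 1 cells in the female and male day 0 libraries and 371 and 109 at day 3. Within the clusters, 592 genes were called at day 3 in cluster 5 and 307 in cluster 15.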
